A study of Homo sapiens with 12 samples.

How the data were processed

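RNA sequencing libraries from 12 samples of HaCaT cells, an immortalised human keratinocyte line, were used. The labels place them in 4 groups of 3: untreated cells, cells given M5, cells given M5 and lefamulin, and cells given M5 and retapamulin. The labels do not say what M5 contained, and they give no dose, time or solvent. The extraction text of the labels describes mouse epidermis, which does not match the HaCaT source named for every sample, so it was not used. The batch label is the same word for all samples, and the replicate numbers are not said to mark shared cultures, so no block was fitted.

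The authors named HISAT2 and HTSeq as their processing tools; versions and the genome build are not given in the sources used here. The count table deposited by the authors holds whole-number counts for 22545 gene symbols, 1 column per sample, with no normalization. The second deposited table holds FPKM for the same genes and samples. For all 20422 genes with a count in 2 or more libraries, the deposited FPKM equalled the count divided by a fixed gene length and by the column total of the count table, within a coefficient of variation of 0.001. Of the 22545 identifiers, 21252 were current RefSeq symbols. Without a stated build no coordinates are given, and strandedness was not stated, so antisense and overlapping genes such as INSIG1-DT and CD27-AS1 are uncertain. Counts of close paralogs (SERPINB3 and SERPINB4, S100A7 and S100A7A, DEFB4A, KRT6A and KRT6B, the SPRR2 genes) are uncertain as well, since shared reads could not be examined.

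Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 14207 genes tested and 8338 not tested. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries. Each of 6 comparisons was tested by edgeR with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p under 0.05 is called. Fold changes are log2 values; standard errors (SE) and 95% intervals came from the fit. Levels are CPM (counts scaled to a common library size) on TMM-scaled library sizes, as mean ± SD over 3 libraries. Since all libraries of a group may come from 1 culture, the p-values may measure technical spread only. Where a group had 0 counts in all libraries, the fold is a lower bound against 3 counts over the group, which correspond to 0.0255 to 0.0296 CPM. With 1 to 3 counts, the fold is a ratio with a 95% counting interval. Such intervals and floors cover counting error only.

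Gene lists for keratinocyte, immune, metabolic, stress and cell cycle processes, the hnRNP family and markers of other cell types were written from general knowledge before the data were examined. So were the comparisons, the tests, the rule for named genes and the alternative settings. The 37 lists include the title genes TNF and HNRNPU. Of 737 list entries, 700 were matched to the table and 37 were not. The matching rule was set after the table was seen: an exact symbol, or, for the 13 mitochondrially encoded mRNAs, the RefSeq synonym. The 32 lists with at least 3 tested members, the title genes aside, were tested in 4 comparisons with fry of limma 3.58.1 on log2 CPM with a prior count of 2, and adjusted over all lists and comparisons. The fry p-value tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Each list was tested again with camera, which compares it with the other genes tested, with a preset correlation of 0.01 and with an estimated correlation. A list p given with an estimated correlation is that of camera. A call lost with camera may thus reflect this other question as well as the correlation. Members are counted as risen or fallen by edgeR over all genes tested. The 4 marker lists of other cell types had 2 tested members each and were not tested as lists.

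Named genes were chosen by a fixed rule. In M5 against untreated and in each compound against M5, they are the 8 called genes with the largest rise and the 8 with the largest fall, with a group mean of at least 5 CPM and no overlap between the libraries of the groups. For lefamulin against retapamulin the number was 5 each way. In each list up to 2 called members with the largest rise and 2 with the largest fall were added, or the member with the smallest p where none was called, and TNF and HNRNPU in every comparison. Genes outside the rule are said to have been chosen after their values were seen. Not every gene named by the rule is printed.

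Overlaps between comparisons that share the M5 libraries were set beside 20 simulated data sets with no group differences, beside the overlap of independent lists, and beside recounts with separate M5 libraries. Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, other filters, fits of 2 groups, a block for replicate number, limma on log2 FPKM with pseudocounts of 1 and 0.1, a fold minimum, camera, and leaving out each library. Library totals alone and separate M5 libraries were chosen after seeing the data. On data simulated like M5 with lefamulin against M5, edgeR recovered 54% of 50 genes changed by 0.25 on the log2 scale, 74% of those changed by 0.5, 86% of those changed by 1 and 98% of those changed by 2, with 8 false calls among 13394 unchanged genes. In the same comparison fry gave p under 0.05 for 1 of 100 lists with no change. The simulated genes varied independently, so lists of correlated genes were not covered. Only 200 genes were changed, as many raised as lowered, whereas edgeR called 9647 in the real comparison. Scaling and false calls where most genes change were therefore not covered. For a simulated list with as many genes raised as lowered, by equal folds, fry still gave a directional p of 2.59e-05. Camera gave p of 0.192 with the preset and 0.205 with the estimated correlation. A small fry p for a list that is split in direction therefore does not show a common direction. For trends with GC content, values from a GENCODE human transcript set were matched by symbol to 90.1% of the tested genes.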

Results

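Gene expression was measured by RNA sequencing in 12 libraries of HaCaT cells, an immortalised human keratinocyte line, in 4 groups of 3. Cells were untreated, given M5, given M5 with lefamulin, or given M5 with retapamulin. M5 is a name in common use for a mix of proinflammatory cytokines that gives cultured keratinocytes psoriasis-like features, but its composition here is not given in the sources used here. Lefamulin and retapamulin are pleuromutilin antibiotics that share a tricyclic core and differ in their side chains. Doses and times are not given in the sources used here, so it is not known whether those of the compounds were matched. The title of the series concerns pleuromutilins, psoriasis, hnRNP-U (gene HNRNPU) and TNF-α (gene TNF).

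Libraries held 35110519 to 37520999 counted reads or fragments and 17009 to 17955 genes with a count. The 20 genes with the most counts took 7.55% to 8.84% of a library, and mitochondrially encoded genes took group means of 4.32%, 3.90%, 4.05% and 3.83% in untreated, M5, lefamulin and retapamulin libraries. On the first principal component, with 62.9% of the variance, untreated libraries lay between -82.1 and -80.9, M5 libraries between -24.1 and -23.4, lefamulin libraries at or under 44.5, and retapamulin libraries between 60.1 and 61.4. The biological coefficient of variation was 0.0488, and the median SE of a fold change of M5 against untreated was 0.07 on the log2 scale. Of 13 mitochondrially encoded mRNAs, edgeR called 0 in M5 against untreated, and 0 had an unadjusted p under 0.05; the member with the smallest p, ATP6, differed by -0.09. ATP6 in M5 versus untreated was called without the filter on low counts, with the replicate block, on log2 FPKM with the filter, on library totals alone and without M5 replicate 2, with adjusted p from 0.00406 to 0.0364.

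M5 against untreated asks what M5 does to these cells. M5 raised chemokines, cytokines, antimicrobial peptides and targets of NF-kB and STAT3, and lowered genes of DNA replication. CSF3, which encodes the granulocyte growth factor G-CSF, rose from 0.0336 ± 0.0381 to 317 ± 2.74 CPM (SD, n = 3 in every group). Of 14207 genes tested, edgeR called 4022 higher and 3817 lower, of which 720 and 785 changed at least 2-fold. Across genes the fold change went up with abundance (Spearman correlation 0.33), and the cause of this trend was not tested. TNF rose from 0.468 ± 0.0697 to 5.12 ± 0.340 CPM (log2 fold change 3.44, SE 0.25). HNRNPU rose from 880.0 ± 15.2 to 974 ± 31.2 CPM (0.15, SE 0.03, edgeR adjusted p = 1.2e-04), a call that ended on library totals and on FPKM, with adjusted p from 0.37 to 0.422 there and from 1.4e-08 over all alternatives.

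The genes with the largest rises by fitted fold change encode immune mediators and serpins. SERPINB3 and SERPINB4 encode protease inhibitors of the serpin family known as squamous cell carcinoma antigens, and their counts are uncertain because they are close paralogs. SERPINB3 reached 544 ± 40.2 CPM, 64014-fold above 1 count in untreated cells (95% counting interval 11489 to 2528450), and SERPINB4 reached 832 ± 50.7 CPM. S100A8, a subunit of calprotectin, reached 113 ± 1.68 CPM, 4428-fold above 3 counts (interval 1515 to 21473). Untreated libraries held no counts of IL19, CCL20, IL20 and PPBP. Their levels after M5 were at least 1753-fold, 572-fold, 416-fold and 329-fold higher than the floor over the group. The largest falls included CPA4, a carboxypeptidase, at -4.97 (SE 0.14), ANK1 at -4.70 (SE 0.17) and MAB21L4 at -4.70 (SE 0.25).

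Inflammatory lists rose together after M5. Of 12 tested chemokine genes 11 rose, with a median log2 fold change of 6.84, or 6.03 with the 2 genes without untreated counts at their bounds (fry adjusted p = 9.9e-15); CXCL5, a neutrophil attractant, was 2693-fold higher (interval 745 to 22246), and CCL26 fell by 1.12 on the log2 scale. Of 26 cytokine and growth factor genes 22 rose and 4 fell (adjusted p = 9.9e-15), among the latter IL36RN, an antagonist of IL-36, which fell by 3.01. All 13 antimicrobial peptide and alarmin genes rose (1.2e-13), including PI3, which encodes the elastase inhibitor elafin, by 10.24 (SE 0.26). All 23 NF-kB feedback genes and targets rose (1.2e-13), including TNIP3 by 9.38 (SE 0.48). Of 20 genes of the STAT3 axis 16 rose and 2 fell (2.4e-13), of 14 matrix metalloproteinase and plasminogen genes 10 rose and 3 fell (2.4e-13), and of 12 genes for hyaluronan and ligands of the epidermal growth factor receptor 10 rose and 2 were not called (1.4e-12). Examples are MMP1, an interstitial collagenase, by 5.94 (SE 0.39), HAS3, a hyaluronan synthase, from 46.5 ± 2.78 to 949.5 ± 24.2 CPM, and HBEGF by 3.81 (SE 0.07). Calls of these lists held with an estimated correlation. Of 29 interferon-stimulated genes 16 rose and 5 fell (median 0.25, 0.13 on library totals, 3.3e-08, adjusted p = 0.13 with an estimated correlation): OASL rose by 4.75 (SE 0.16), whereas IFIT1 fell by 1.82.

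Epidermal lists were split after M5. Of 19 genes of keratinocyte differentiation and the cornified envelope 8 rose and 7 fell. The median of this list was -0.03 (-0.15 on library totals), its mean 1.61 and its test upward (fry adjusted p = 8.5e-07, adjusted p = 0.895 with an estimated correlation). IVL (involucrin) fell by 4.30 and FLG (filaggrin) fell by 2.56, while SPRR2E, a small proline-rich gene uncertain as a paralog, was 197-fold above 2 counts (interval 54.0 to 1629). Of 4 stress keratins KRT6A rose by 1.09 and KRT6B was 299-fold above 1 count (interval 53.2 to 11841), both uncertain as paralogs, while KRT16 fell by 2.96 and KRT17 fell by 0.62 (list upward, median 0.23, 0.11 on library totals, adjusted p = 4.4e-04, and adjusted p = 0.941 with an estimated correlation). Of 15 basal keratinocyte genes 10 rose, including CDH3 (P-cadherin) from 314 ± 4.71 to 936 ± 8.95 CPM, and 5 fell, including KRT5 from 1632 ± 46.3 to 637 ± 25.3 CPM (list upward, adjusted p = 2.4e-08, adjusted p = 0.323 with an estimated correlation). Of 5 simple epithelial keratins 2 rose and 2 fell, with a median of 0.17 (0.05 on library totals) and a test downward that did not pass (adjusted p = 0.242). Of 18 genes of TGF-beta and epithelial-mesenchymal transition 7 rose, such as INHBA by 2.09 (SE 0.05), and 7 fell, such as CCN2, which fell by 2.66 (list upward, adjusted p = 5.4e-06, adjusted p = 0.811 with an estimated correlation); the median was 0.06 but -0.06 on library totals.

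Among metabolic and stress lists, 25 of 27 glycolysis and hypoxia genes rose (fry adjusted p = 2.8e-10), all 17 endoplasmic reticulum chaperone genes rose (9.2e-11), and 14 of 20 immediate early genes rose while 2 fell (3.7e-10). Examples are BNIP3 by 2.33 (SE 0.09), XBP1, a transcription factor of the unfolded protein response, by 1.44 (SE 0.03), and IER3 by 2.01 (SE 0.03). These calls held with an estimated correlation. Of 25 cholesterol genes 19 rose and 4 fell (median 0.35, 0.23 on library totals, adjusted p = 1.7e-09, adjusted p = 0.0666 with an estimated correlation), with STARD4, a sterol carrier, rising by 1.44 (SE 0.05). Of 12 fatty acid synthesis genes 8 rose and 2 fell (median 0.16, 0.04 on library totals, 4.2e-05, adjusted p = 0.349 with an estimated correlation). Of 31 ATF4 genes 19 rose, such as CEBPB by 2.21 (SE 0.05), and 10 fell, such as the amino acid transporter SLC7A5, which fell by 0.83 (list upward, median 0.26, 0.14 on library totals, 6.5e-07, adjusted p = 0.272 with an estimated correlation). Of 26 lysosome and autophagy genes 14 rose and 5 fell (2.5e-06, adjusted p = 0.499 with an estimated correlation), with CTSB (cathepsin B) rising from 327 ± 8.42 to 2087 ± 47.2 CPM; the median of 0.11 was -0.01 on library totals. Of 20 NRF2 targets 9 rose and 6 fell (6.6e-08, adjusted p = 0.499 with an estimated correlation), with a median of 0.10 that was -0.02 on library totals, and AKR1C2, an aldo-keto reductase, rose by 4.46 (SE 0.06). Of 12 heat shock genes 8 rose and 2 fell (median 0.16, 0.05 on library totals, 2.6e-06, adjusted p = 0.24 with an estimated correlation), and of 3 pregnane X receptor targets 2 rose and 1 fell (3.1e-07, adjusted p = 0.444 with an estimated correlation).

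Cell cycle lists fell after M5. Of 30 DNA replication genes 21 fell and 3 rose, with a median of -0.19 (-0.31 on library totals, fry adjusted p = 8.7e-07). This call held narrowly with an estimated correlation (camera adjusted p = 0.0498). CCNE1 (cyclin E1) was among those that rose, by 0.57 (SE 0.11). Of 30 mitosis genes 21 fell and 1 rose, with a median of -0.20 (-0.32 on library totals, adjusted p = 2.4e-05, adjusted p = 0.202 with an estimated correlation). Of 20 p53 targets 11 rose and 5 fell (median 0.24, 0.13 on library totals, 2e-08, adjusted p = 0.202 with an estimated correlation). Of 23 members of the hnRNP family, RNA-binding proteins that include HNRNPU, 9 rose and 5 fell (list upward, adjusted p = 0.0205, adjusted p = 0.797 with an estimated correlation); the median of 0.05 was -0.07 on library totals. The hnRNP call was lost without untreated replicate 1 (0.0666), M5 replicate 1 (0.0623) or M5 replicate 3 (0.0516), with 3.3e-05 to 0.797 over its alternatives. Lists that did not pass were nuclear OXPHOS subunits (2 rose and 12 fell of 34, adjusted p = 0.125), the mitochondrial ribosome (5 rose and 5 fell of 26, adjusted p = 0.554, median -0.00 and 0.01 with RLE), cytosolic ribosomal proteins (1 rose and 2 fell of 30, adjusted p = 0.85, median 0.00, mean -0.01 and -0.12 on library totals), mitochondrially encoded mRNAs (adjusted p = 0.721) and aryl hydrocarbon receptor targets (2 rose and 3 fell of 5, adjusted p = 0.515, median -0.52 with an upward test). Without untreated replicate 1 the OXPHOS list (0.00897) and the mitochondrial ribosome (0.00635) passed, and without untreated replicate 2 the aryl hydrocarbon receptor targets passed (0.0207); over their alternatives the p ranged from 0.00897 to 0.718, from 0.00635 to 0.943 and from 0.00149 to 0.776.

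The 26 called lists of 32 comprised 24 upward and 2 downward, and 11 calls held with an estimated correlation. Adjusted over the list alone, the counts of risen and fallen genes were the same for all lists but 8: 17 STAT3 genes, 10 NRF2 targets, 15 immediate early genes, 10 hnRNP genes and 8 TGF-beta genes rose, 11 OXPHOS, 6 lysosome and 7 hnRNP genes fell, and edgeR called 0 cytosolic ribosomal genes, of which 1 rose and 2 fell at an unadjusted p under 0.05. The groups did not overlap for 8408 genes (59.2%, against 10% by chance). The share of higher genes among those called was 51.3%, but 31.5% on library totals, where the median of all genes lay at -0.14 instead of -0.02.

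**Figure D1:**
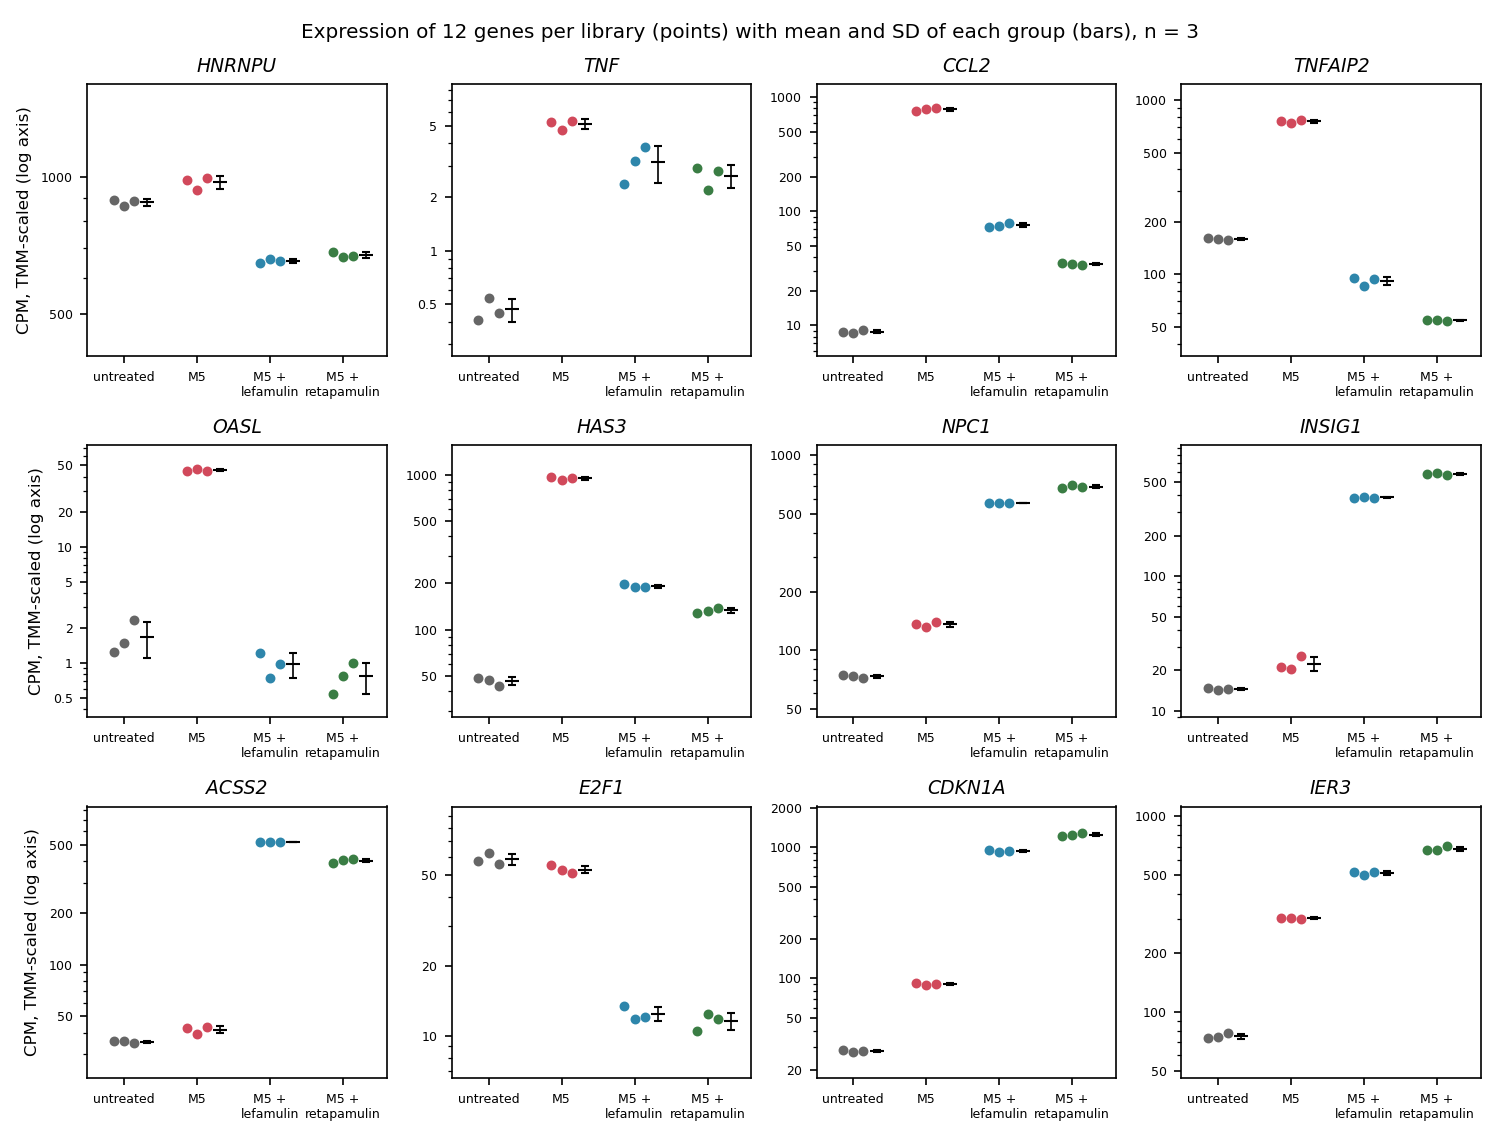
Expression of 12 genes in each library (points), in CPM on TMM-scaled library sizes (log axis), for untreated, M5, M5 with lefamulin and M5 with retapamulin, with the mean and SD of each group (bars, n = 3). TNF rose from 0.468 CPM in untreated cells to 5.12 with M5 and lay at 3.12 and 2.63 with the compounds, whereas IER3 rose with M5 to 302 CPM and further to 513 and 683 CPM.

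Lefamulin added to M5 is compared with M5 alone to ask what the compound changes. Lefamulin raised genes of cholesterol and fatty acid synthesis together and immediate early genes, and lowered chemokines, antimicrobial peptides and DNA replication genes. TNF fell from 5.12 ± 0.340 to 3.12 ± 0.736 CPM (log2 fold change -0.71, SE 0.19, edgeR adjusted p = 0.00155). HNRNPU fell from 974 ± 31.2 to 654 ± 6.81 CPM (-0.58, SE 0.03, adjusted p = 6.8e-15). Of 14207 genes tested, edgeR called 4774 higher and 4873 lower, of which 1291 and 697 changed at least 2-fold. Among the largest rises were PRR9, a proline-rich gene of the epidermal differentiation region, by 6.49 (SE 0.41), TRPV3, a heat-gated ion channel of keratinocytes, by 6.37 (SE 0.28) to 15.2 ± 0.134 CPM, and PNPLA3 by 5.32 (SE 0.28). Among the largest falls were IL19, from 44.7 ± 1.70 to 0.346 ± 0.153 CPM, S100A8, from 113 ± 1.68 to 1.32 ± 0.420 CPM, OASL, from 45.2 ± 0.878 to 0.973 ± 0.241 CPM, and FBLN5, from 21.2 ± 2.10 to 0.517 ± 0.140 CPM. The groups did not overlap for 10120 genes (71.2%, against 10% by chance).

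Retapamulin added to M5 is compared with M5 alone in the same way. Retapamulin too raised genes of cholesterol and fatty acid synthesis and immediate early genes, and lowered chemokines, antimicrobial peptides and DNA replication genes. TNF fell from 5.12 ± 0.340 to 2.63 ± 0.396 CPM (-0.96, SE 0.19, edgeR adjusted p = 8e-05), and HNRNPU fell from 974 ± 31.2 to 674 ± 9.29 CPM (-0.53, SE 0.03, adjusted p = 2.4e-14). Of 14207 genes tested, edgeR called 4842 higher and 5404 lower, of which 1393 and 1231 changed at least 2-fold. The share of higher genes was 47.3%, but 37.4% on library totals, where the median of all genes lay at -0.19 instead of -0.05. The largest rises included PRR9, to 58.4 ± 1.23 CPM, TRPV3, to 66.7 ± 0.973 CPM, SPRR1A, a cornified envelope precursor, from 0.313 ± 0.307 to 16.1 ± 0.639 CPM, and IL36RN, from 0.468 ± 0.0930 to 19.0 ± 1.44 CPM. The largest falls included IL19, to 0.0881 ± 0.0885 CPM, S100A8, to 0.936 ± 0.104 CPM, TCIM, from 6.22 ± 0.244 to 0.0496 ± 0.0452 CPM, and ADAMTS4, an aggrecan-degrading protease, by -5.53 (SE 0.34). The groups did not overlap for 10489 genes (73.8%, against 10% by chance).

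**Figure D2:**
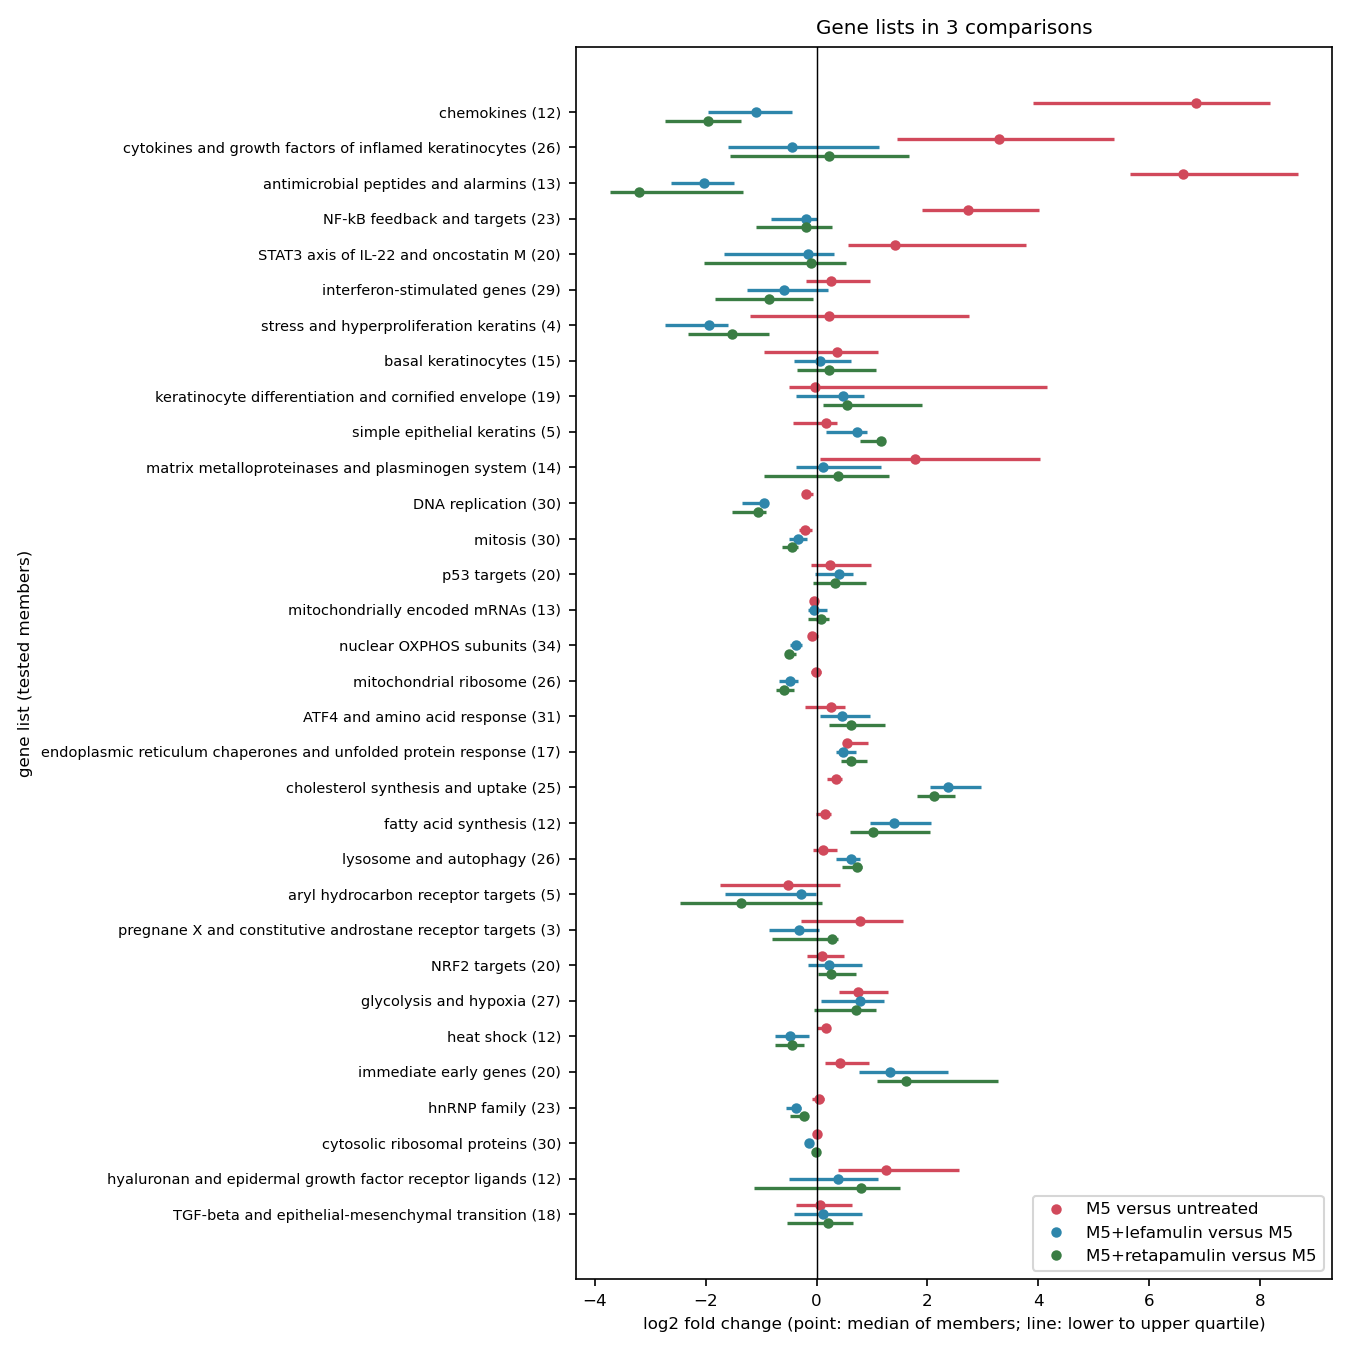
Median log2 fold change (points) and lower to upper quartile (lines) of the members of each gene list, with the number of tested members, in M5 against untreated, M5 with lefamulin against M5 and M5 with retapamulin against M5. The cholesterol list had medians of 0.35, 2.37 and 2.11, and the antimicrobial list 6.60, -2.03 and -3.20.

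Lipid synthesis genes rose with both compounds. Of 25 genes of cholesterol synthesis and uptake, 24 rose with lefamulin and 1 was not called (median 2.37, fry adjusted p = 6e-14), and 24 rose and 1 fell with retapamulin (median 2.11, adjusted p = 7.4e-14). INSIG1, which retains the sterol sensor of the endoplasmic reticulum, rose from 22.3 ± 2.70 CPM with M5 to 385 ± 3.16 with lefamulin and 575 ± 9.60 with retapamulin. PMVK (phosphomevalonate kinase) fell with retapamulin, by -0.41 (SE 0.11). Of 12 fatty acid synthesis genes 11 rose with lefamulin (median 1.40, adjusted p = 1.7e-12) and 12 with retapamulin (median 1.02, adjusted p = 2.5e-12). ACSS2, which makes acetyl-CoA from acetate, rose from 41.9 ± 2.06 to 521 ± 1.22 and 404 ± 9.69 CPM, and LPIN1, a phosphatidate phosphatase, from 33.2 ± 1.80 to 466 ± 2.99 and 513 ± 10.3 CPM. These 4 calls held with an estimated correlation. Lefamulin exceeded retapamulin over the cholesterol list, with 17 genes higher, 2 lower and a median difference of 0.21 (adjusted p = 1.6e-06, adjusted p = 0.0718 with an estimated correlation), and over the fatty acid list, with 6 higher, 1 lower and a median difference of 0.09 (0.05 with RLE, 0.17 on library totals, adjusted p = 4.5e-05, adjusted p = 0.237 with an estimated correlation). TM7SF2, a sterol reductase, was higher with lefamulin by 1.40 (95% interval 1.23 to 1.58), whereas INSIG1 was lower by -0.58 (-0.66 to -0.50).

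Lists of secreted inflammatory mediators fell in part. Of 12 chemokine genes 9 fell with lefamulin (median -1.08, fry adjusted p = 4.7e-11) and 12 with retapamulin (median -1.95, adjusted p = 3.4e-12). CCL2, a monocyte attractant, fell to 75.9 ± 3.06 and 34.7 ± 0.721 CPM (-3.37, SE 0.04, and -4.50, SE 0.04). Of 13 antimicrobial peptide genes 12 fell and 1 rose with each compound (medians -2.03 and -3.20, adjusted p = 9.8e-10 and 2.9e-10); the gene that rose was RNASE7, an antimicrobial ribonuclease, by 4.03 (SE 0.08) and 4.55 (SE 0.07). With an estimated correlation the chemokine calls held at camera adjusted p = 0.0212 and 0.0148, and the antimicrobial calls at 0.0447 and 0.04645. Retapamulin gave lower chemokine levels than lefamulin, with 7 genes higher and 2 lower with lefamulin (median difference 0.69, adjusted p = 2.9e-08), which held with an estimated correlation. For antimicrobial peptides 7 were higher and 2 lower (0.31, adjusted p = 6.8e-05, adjusted p = 0.179 with an estimated correlation).

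Cytokine and growth factor genes went both ways, with 10 rising and 14 falling of 26 with lefamulin and 13 rising and 12 falling with retapamulin. Medians were -0.45 and 0.22 (for retapamulin 0.09 on library totals), means -0.45 and -0.22, and fry was upward for both (fry adjusted p = 3.7e-06 and 2.2e-09), calls lost at adjusted p = 0.742 and adjusted p = 0.521 with an estimated correlation. IL20 fell from 10.6 ± 0.797 CPM to 0.272 ± 0.101 and 0.365 ± 0.0610 CPM, whereas the antagonists IL1RN and IL36RN rose: IL1RN by 3.75 (SE 0.13) and 4.67 (SE 0.12), and IL36RN by 4.25 (SE 0.19) and 5.33 (SE 0.19). Lefamulin lay below retapamulin over this list (5 higher and 14 lower, median difference -0.22, -0.13 on library totals, adjusted p = 6e-08), which held with an estimated correlation.

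Of 23 NF-kB feedback genes and targets 13 fell with each compound, and 4 rose with lefamulin and 9 with retapamulin. Medians were -0.18 and -0.19 (for retapamulin -0.32 on library totals, fry adjusted p = 2.1e-08 and 5.4e-09; adjusted p = 0.258 and adjusted p = 0.499 with an estimated correlation). TNFAIP2 fell from 755 ± 15.9 to 91.5 ± 4.73 and 54.5 ± 0.389 CPM, and IRAK2 rose by 1.51 (SE 0.22) and 1.33 (SE 0.23). Of 20 STAT3 axis genes 8 rose and 11 fell with each compound. The lefamulin test did not pass (adjusted p = 0.0928, upward with a median of -0.16), and the retapamulin test was upward with a median of -0.10 (-0.06 with RLE, -0.23 on library totals) and a mean of -0.56 (adjusted p = 8.9e-05, adjusted p = 0.953 with an estimated correlation). FOSL1, an AP-1 subunit, rose by 2.02 (SE 0.04) and 2.71 (SE 0.04), and SERPINB4 fell (-3.22 and -4.88). Of 29 interferon-stimulated genes 19 fell with each compound, and 7 and 5 rose. The lefamulin median was -0.58 (adjusted p = 1.9e-08, adjusted p = 0.0718 with an estimated correlation), and the retapamulin median was -0.86 (adjusted p = 6.4e-10, adjusted p = 0.0488 with an estimated correlation). STAT2 rose by 1.30 (SE 0.04) and 1.29 (SE 0.04), and IFI44 fell (-3.71 and -3.19). Interferon-stimulated genes were higher with lefamulin than with retapamulin (12 higher and 2 lower, median difference 0.20, adjusted p = 8.5e-07), which held.

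Immediate early genes, which respond within minutes to growth factors or stress, rose with both compounds. Of 20 genes 19 rose with lefamulin (median 1.32, fry adjusted p = 1.4e-12), and 19 rose and 1 fell with retapamulin (median 1.61, adjusted p = 2.3e-13). KLF6 rose from 33.2 ± 0.137 to 207 ± 4.36 and 490.4 ± 7.23 CPM, and FOSB from 3.34 ± 0.545 to 30.4 ± 2.57 and 32.4 ± 0.698 CPM. All 16 called of 17 endoplasmic reticulum chaperone genes rose with each compound (medians 0.48 and 0.63, adjusted p = 6.4e-10 and 8.8e-11), including HERPUD1 by 1.43 (SE 0.04) and 1.87 (SE 0.04). These 4 calls held with an estimated correlation, those of the chaperones at camera adjusted p = 0.0488 and 0.0428. Of 31 ATF4 genes 21 rose and 5 fell with lefamulin (median 0.47, adjusted p = 3.8e-09, adjusted p = 0.0718 with an estimated correlation). With retapamulin 24 rose and 6 fell (median 0.61, adjusted p = 5.4e-10, adjusted p = 0.0498 with an estimated correlation). CTH, an enzyme of cysteine synthesis, rose with lefamulin by 1.89 (SE 0.09), and SLC7A5 fell by 1.04 with each compound. Of 12 heat shock genes 10 fell and 2 rose with each compound (medians -0.49 and -0.44, adjusted p = 2.9e-10 and 6.4e-10, adjusted p = 0.0718 and adjusted p = 0.0974 with an estimated correlation). HSPD1, a mitochondrial chaperonin, fell from 1027 ± 16.7 to 525 ± 8.75 and 554 ± 2.59 CPM.

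All 30 DNA replication genes fell with each compound (medians -0.95 and -1.05, fry adjusted p = 1.0e-12 and 5.8e-13), calls that held with an estimated correlation. E2F1, a transcription factor of S-phase entry, fell from 52.8 ± 2.05 to 12.5 ± 0.880 and 11.5 ± 1.00 CPM. Mitosis genes fell less: 24 of 30 fell with lefamulin (median -0.34, adjusted p = 9.5e-08, adjusted p = 0.155 with an estimated correlation) and 26 with retapamulin (median -0.45, adjusted p = 1.1e-08, adjusted p = 0.136 with an estimated correlation). KIF20A, a mitotic kinesin, fell (-0.83 and -1.22), and CDC25C, a phosphatase of mitotic entry, rose with lefamulin by 0.62 (SE 0.08). Of 20 p53 targets 12 rose and 4 fell with lefamulin (median 0.41, adjusted p = 3.5e-09, adjusted p = 0.202 with an estimated correlation) and 13 rose and 4 fell with retapamulin (median 0.33, 0.19 on library totals, adjusted p = 2e-09, adjusted p = 0.202 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 90.4 ± 2.05 to 935 ± 11.7 and 1242 ± 29.9 CPM.

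Of 23 hnRNP genes 22 fell with lefamulin (median -0.37, fry adjusted p = 1.6e-09, adjusted p = 0.053 with an estimated correlation) and 19 fell and 1 rose with retapamulin (median -0.23, -0.37 on library totals, adjusted p = 2.3e-08, adjusted p = 0.155 with an estimated correlation). Counted from the lowest fold change, HNRNPU was member 6 of 23 with lefamulin and member 3 of 23 with retapamulin. HNRNPAB fell (-0.69 and -0.75), and HNRNPC fell (-0.68 and -0.56). Of 30 cytosolic ribosomal protein genes 23 fell with lefamulin (median -0.14, adjusted p = 0.00104, adjusted p = 0.499 with an estimated correlation). With retapamulin 6 rose and 7 fell (adjusted p = 0.475), with a median of -0.01 that was 0.02 with RLE. RPS2 fell (-0.44 and -0.35).

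Nuclear genes for mitochondrial proteins fell. Of 34 nuclear OXPHOS subunits 31 fell with lefamulin (median -0.37, fry adjusted p = 5.2e-07, adjusted p = 0.167 with an estimated correlation) and 33 with retapamulin (median -0.49, adjusted p = 1.2e-07, adjusted p = 0.168 with an estimated correlation). Of 26 genes of the mitochondrial ribosome 24 fell and 1 rose with each compound (medians -0.48 and -0.59, adjusted p = 1.1e-07 and 2.3e-08, adjusted p = 0.13 and adjusted p = 0.135 with an estimated correlation). MRPL16 fell from 57.7 ± 1.20 to 26.7 ± 1.26 and 22.0 ± 0.507 CPM, and MRPL49 rose by 0.74 (SE 0.04) and 0.48 (SE 0.04). Of 27 glycolysis and hypoxia genes 19 rose with each compound, and 4 and 7 fell (medians 0.78 and 0.70, adjusted p = 4.6e-09 and 1.4e-08, adjusted p = 0.168 and adjusted p = 0.235 with an estimated correlation). ENO2, a glycolytic enolase, rose from 3.11 ± 0.402 to 17.3 ± 0.0775 and 23.8 ± 1.78 CPM. Of 26 lysosome and autophagy genes 22 rose with each compound, and 2 and 3 fell (medians 0.62 and 0.73, adjusted p = 3.5e-09 and 1.6e-09, adjusted p = 0.0869 with an estimated correlation for both). NPC1, a lysosomal cholesterol exporter, rose by 2.08 (SE 0.03) and 2.35 (SE 0.03), and CTSB fell (-1.93 and -2.16).

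Epidermal lists moved in several directions. Of 19 differentiation genes 10 rose and 2 fell with lefamulin (median 0.47, fry adjusted p = 2.6e-08, adjusted p = 0.21 with an estimated correlation), and 12 rose and 1 fell with retapamulin (median 0.55, adjusted p = 3.4e-09, adjusted p = 0.04999 with an estimated correlation). SPRR1A rose by 4.14 (SE 0.34) and 5.66 (SE 0.34). All 4 stress keratins fell with lefamulin (median -1.94, adjusted p = 3.8e-09, adjusted p = 0.11 with an estimated correlation) and 3 with retapamulin (median -1.53, adjusted p = 4e-08, adjusted p = 0.202 with an estimated correlation), such as KRT17 from 18.8 ± 0.731 to 4.09 ± 0.362 and 4.62 ± 0.482 CPM. Of 15 basal genes 8 rose and 6 fell with lefamulin (list upward, adjusted p = 1.4e-05, median 0.06, 0.02 on library totals, mean -0.02, adjusted p = 0.74 with an estimated correlation), and 9 rose and 5 fell with retapamulin (median 0.23, 0.09 on library totals, adjusted p = 1.1e-08, adjusted p = 0.459 with an estimated correlation). TP63, a transcription factor of basal keratinocytes, fell from 228 ± 10.3 to 114 ± 2.98 and 86.5 ± 3.52 CPM. Of 5 simple epithelial keratins 3 rose with each compound (medians 0.72 and 1.16, adjusted p = 9.4e-08 and 4.6e-09, adjusted p = 0.346 and adjusted p = 0.347 with an estimated correlation), with KRT8 at 5062 ± 70.4 and 6713 ± 124 CPM against 2679.9 ± 79.8 CPM with M5.

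Among lists of the cell surroundings, 7 of 14 matrix metalloproteinase and plasminogen genes rose and 6 fell with lefamulin (median 0.12, 0.07 on library totals, fry adjusted p = 1.2e-07, adjusted p = 0.509 with an estimated correlation). With retapamulin 8 rose and 6 fell (median 0.39, 0.25 on library totals, adjusted p = 4e-09, adjusted p = 0.411 with an estimated correlation). PLAU (urokinase) rose from 175 ± 0.547 to 748 ± 4.23 and 1342 ± 25.5 CPM, and PLAT (tissue plasminogen activator) fell (-1.39 and -1.87). Of 12 hyaluronan and receptor ligand genes 7 rose and 4 fell with lefamulin (median 0.38, adjusted p = 4.3e-07, adjusted p = 0.323 with an estimated correlation), and 8 rose and 4 fell with retapamulin (median 0.80, adjusted p = 9.8e-10, adjusted p = 0.179 with an estimated correlation). HAS2 rose by 2.15 (SE 0.09) and 3.55 (SE 0.08), and HAS3 fell (-2.31 and -2.84). Of 18 TGF-beta genes 9 rose and 8 fell with lefamulin, with a median of 0.12 (0.07 on library totals) and a downward test (adjusted p = 0.00596, adjusted p = 0.964 with an estimated correlation, 0.319 without M5 replicate 3, and 0.00952 to 0.964 over the alternatives). With retapamulin 8 rose and 6 fell, with a median of 0.21 (0.07 on library totals) and a downward test that did not pass (adjusted p = 0.159); it passed without retapamulin replicate 2 (0.0201) or replicate 3 (0.0133), within a range of 0.0133 to 0.835. TGFB2 fell (-1.97 and -3.32).

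Of 20 NRF2 targets 10 rose and 6 fell with lefamulin (median 0.23, fry adjusted p = 5.2e-07, adjusted p = 0.379 with an estimated correlation), and 13 rose and 5 fell with retapamulin (median 0.26, 0.13 on library totals, adjusted p = 2.9e-08, adjusted p = 0.195 with an estimated correlation). HMOX1 (heme oxygenase 1) rose from 0.206 ± 0.146 to 1.41 ± 0.297 and 5.40 ± 0.362 CPM. Of 5 aryl hydrocarbon receptor targets 1 rose and 2 fell with lefamulin (median -0.28, adjusted p = 2.1e-09, adjusted p = 0.499 with an estimated correlation), and 2 rose and 3 fell with retapamulin (median -1.36, adjusted p = 4.3e-10, adjusted p = 0.545 with an estimated correlation). CYP1B1, a cytochrome P450, fell (-1.96 and -2.49). Of 3 pregnane X receptor targets 1 rose and 1 fell with each compound, upward by fry (adjusted p = 0.0218 and 6.6e-04) with medians of -0.32 and 0.28 (for retapamulin 0.14 on library totals) and means of -0.43 and -0.37. These calls were lost at adjusted p = 0.999776 and adjusted p = 0.835 with an estimated correlation. They were also lost on leaving out any of the 6 libraries of each comparison, with p from 0.208 to 0.736 and from 0.132 to 0.769, and the lefamulin call was lost with the replicate block (adjusted p = 0.0638, within 0.0282 to 0.999776). ALAS1, the first enzyme of heme synthesis, rose by 0.42 (SE 0.04) and 0.51 (SE 0.04).

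With lefamulin, 30 of 32 lists were called, 16 upward and 14 downward, and 7 calls held with an estimated correlation. With retapamulin, 29 were called, 17 upward and 12 downward, and 10 held. Adjusted over the list alone, 10 chemokine genes fell and 8 interferon-stimulated, 11 NRF2 and 8 hyaluronan or ligand genes rose with lefamulin. With retapamulin 14 NRF2 targets and 6 mitochondrially encoded mRNAs rose and 6 cytosolic ribosomal genes fell; other counts were the same.

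Markers of other cell types were also read in these cells, with 2 tested genes for each type. M5 raised CDH5, an endothelial cadherin, from 15.5 ± 1.08 to 119.6 ± 2.66 CPM and CD68, a macrophage marker, by 1.23 (SE 0.06). It lowered MITF, a melanocyte transcription factor, from 24.4 ± 1.29 to 9.90 ± 1.41 CPM, and VWF, the other endothelial marker, by -3.06 (SE 0.61). Both compounds raised VWF, by 5.35 (SE 0.59) and 5.28 (SE 0.59), COL1A1, a fibroblast collagen, by 1.38 (SE 0.11) and 0.74 (SE 0.11), and CD68, by 0.50 (SE 0.06) and 1.44 (SE 0.05). MITF rose with lefamulin and retapamulin to 14.1 ± 0.922 and 19.8 ± 0.773 CPM, while CD14, the other leukocyte marker, was lower at -2.73 (SE 0.40) and -4.45 (SE 0.59). CDH5 was at 119 ± 2.80 CPM with lefamulin, not called against M5, and was lower with retapamulin at -0.19 (SE 0.05). PMEL of melanocytes lay between 0.682 and 1.54 CPM and PDGFRA of fibroblasts at or under 0.227 CPM in the group means.

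**Figure D3:**
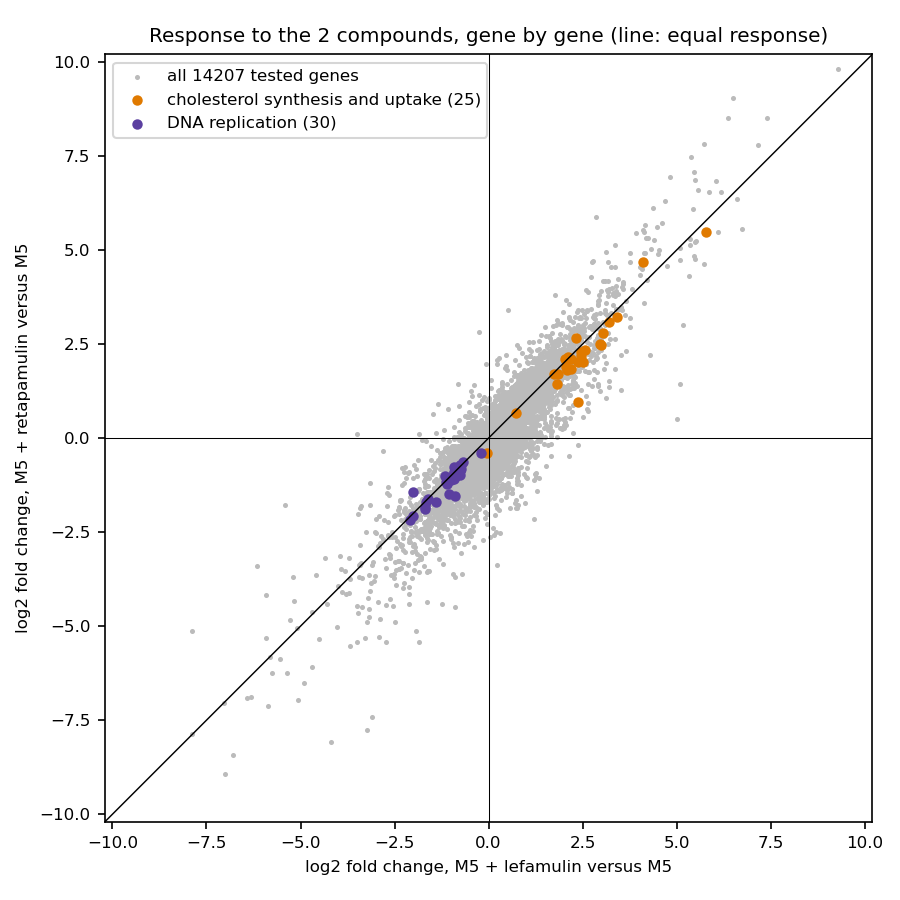
Log2 fold change of all 14207 tested genes with lefamulin (x axis) and retapamulin (y axis), each against M5, with the cholesterol and DNA replication lists in colour and a line of equal response. The 8405 genes called in the same direction lie in the upper right and lower left quadrants, and 131 genes were called in opposite directions.

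Lefamulin was tested directly against retapamulin, both with M5, to ask where the compounds differ. They moved most genes alike in direction, but immediate early genes and cytokine genes were higher with retapamulin, and chemokines and interferon-stimulated genes were higher with lefamulin. TRPV3 reached 15.2 ± 0.134 CPM with lefamulin and 66.7 ± 0.973 CPM with retapamulin, a difference of -2.13 (95% interval -2.27 to -2.00). SERPINB3, uncertain as a paralog, was higher with lefamulin by 2.01 (1.89 to 2.14). TNF differed by 0.24 (-0.16 to 0.65, edgeR adjusted p = 0.341), a difference not detected here, whose interval reaches 0.65. HNRNPU differed by -0.04 (-0.10 to 0.01, adjusted p = 0.228), and it was called lower with lefamulin with RLE (0.0286) and DESeq2 (0.00714), within a range of 0.00714 to 0.438. Of 14207 genes tested, edgeR called 2672 higher and 3017 lower with lefamulin, of which 357 and 105 differed at least 2-fold, and 8518 were not called. Across genes the fold change went down with abundance (Spearman correlation -0.33), against -0.05 and 0.13 for lefamulin and retapamulin against M5. The 8338 genes not tested held a mean of 10398 counts per library with lefamulin and 7685 with retapamulin. How far the excess of 357 over 105 follows this trend was not tested. The share of higher genes was 47.0%, but 36.8% with RLE, 35.3% with DESeq2, 72.8% on library totals and 71.9% on FPKM, and the median of all genes was 0.01, or 0.10 on library totals. The groups did not overlap for 7383 genes (52.0%, against 10% by chance).

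Called with each compound in the same direction were 8405 genes, 4119 raised and 4286 lowered, against 3480.6 for independent lists and at most 1 in simulations that shared the M5 libraries and held no group differences, which give chance with no effect and leave out overlap from shared libraries where effects are present. With separate M5 libraries for each compound the count was 7271 to 7292. At least 2-fold with both were 1030 raised and 604 lowered genes. Of the 8405 genes, 3739 also differed between the compounds, with the larger change by retapamulin in 2977 and by lefamulin in 762. Across genes, which are not independent replicates, the covariance of the fold changes was 0.821, against 0.0279 in the simulations.

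Of 32 lists 28 were called between the compounds, 12 higher and 16 lower with lefamulin, and 4 held with an estimated correlation: chemokines, cytokines, interferon-stimulated genes and immediate early genes. Their highest adjusted p over the alternatives, camera included, were 0.0428, 0.0490, 0.0453 and 0.00727 in that order. Of 20 immediate early genes 14 were lower and 1 higher with lefamulin (median -0.44, fry adjusted p = 4.3e-09), such as EGR1 at 39.8 ± 2.32 and 103 ± 5.53 CPM. Of 19 differentiation genes 10 were lower and 2 higher (median -0.18, -0.09 on library totals, adjusted p = 4.7e-06, adjusted p = 0.0641 with an estimated correlation), such as SPRR2A at 22.7 ± 0.150 and 75.1 ± 6.31 CPM, uncertain as a paralog. Of 15 basal genes 10 were lower and 3 higher (median -0.18, -0.09 on library totals, adjusted p = 3.4e-07, adjusted p = 0.155 with an estimated correlation). Stress keratins (2 of 4 lower, adjusted p = 2.6e-05, adjusted p = 0.155 with an estimated correlation) and simple epithelial keratins (3 of 5 lower, 1 higher, adjusted p = 2.1e-05, adjusted p = 0.317 with an estimated correlation) were lower with lefamulin. So were ATF4 genes (19 of 31 lower, 3 higher, median -0.17, -0.08 on library totals, adjusted p = 6.9e-06, adjusted p = 0.0666 with an estimated correlation), endoplasmic reticulum chaperones (12 of 17 lower, median -0.15, -0.06 on library totals, adjusted p = 1.3e-06, adjusted p = 0.0641 with an estimated correlation), and lysosome genes (11 of 26 lower, 3 higher, median -0.10, -0.01 on library totals, adjusted p = 0.0011, adjusted p = 0.377 with an estimated correlation). The same held for hyaluronan and receptor ligand genes (7 of 12 lower, 2 higher, median -0.26, -0.17 on library totals, adjusted p = 3.7e-08, adjusted p = 0.0869 with an estimated correlation), hnRNP genes (12 of 23 lower, median -0.09, -0.00 on library totals, adjusted p = 5.4e-06, adjusted p = 0.13 with an estimated correlation), and cytosolic ribosomal proteins (24 of 30 lower, median -0.12, -0.03 on library totals, adjusted p = 0.003, adjusted p = 0.359 with an estimated correlation).

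Higher with lefamulin were DNA replication genes (11 of 30 higher, 3 lower, median 0.09, 0.05 with RLE, 0.17 on library totals, fry adjusted p = 4.7e-05, adjusted p = 0.13 with an estimated correlation), mitosis genes (18 of 30 higher, median 0.12, 0.09 with RLE, 0.21 on library totals, adjusted p = 2.1e-04, adjusted p = 0.2 with an estimated correlation), and the mitochondrial ribosome (12 of 26 higher, median 0.11, 0.07 with RLE, 0.20 on library totals, adjusted p = 0.0026, adjusted p = 0.346 with an estimated correlation). Nuclear OXPHOS subunits were higher too (14 of 34, median 0.09, 0.05 with RLE, 0.18 on library totals, adjusted p = 0.0157, adjusted p = 0.458 with an estimated correlation), a call lost with RLE (0.107) and without retapamulin replicate 1 (0.0628), within 0.00601 to 0.458. Aryl hydrocarbon receptor targets had 2 higher and 2 lower of 5 (median 0.53, adjusted p = 1.8e-05, adjusted p = 0.499 with an estimated correlation). In further lists the median turned with a scaling. NF-kB genes had 8 higher and 10 lower, a median of -0.05 (0.04 on library totals) and an upward test (adjusted p = 0.013, adjusted p = 0.923 with an estimated correlation), lost with RLE (0.237) and without retapamulin replicate 1 (0.0594), within 0.0046 to 0.923. STAT3 axis genes had 5 higher and 8 lower, a median of -0.06 (0.03 on library totals), a mean of 0.10 and a downward test (adjusted p = 0.0011, adjusted p = 0.459 with an estimated correlation). Metalloproteinase genes had 3 higher and 7 lower (median -0.06, 0.03 on library totals, adjusted p = 3.7e-06, adjusted p = 0.346 with an estimated correlation), NRF2 targets 4 higher and 7 lower (-0.07, 0.02 on library totals, adjusted p = 7.5e-05, adjusted p = 0.346 with an estimated correlation), and heat shock genes 3 higher and 6 lower (-0.03, 0.06 on library totals, adjusted p = 4.3e-04, adjusted p = 0.499 with an estimated correlation). Glycolysis genes had 10 higher and 7 lower (median 0.01, -0.02 with RLE, adjusted p = 0.0033, adjusted p = 0.74 with an estimated correlation, 0.0557 with RLE, within 0.0037 to 0.74). Not called were TGF-beta genes (5 higher and 8 lower of 18, adjusted p = 0.0789, median -0.06, 0.03 on library totals, mean 0.11), p53 targets (7 higher and 8 lower of 20, adjusted p = 0.2, median 0.05, 0.01 with RLE and 0.13 on library totals, with a downward test), pregnane X receptor targets (adjusted p = 0.0698) and mitochondrially encoded mRNAs (1 lower of 13, adjusted p = 0.935, median -0.01, 0.08 on library totals). Of these the first 3 passed with RLE (0.0153, 0.0155 and 0.0207), within 0.0153 to 0.74, 0.0155 to 0.946 and 0.0207 to 0.92.

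Adjusted over the list alone, 8 antimicrobial, 13 interferon-stimulated, 12 DNA replication, 15 OXPHOS and 2 immediate early genes were higher with lefamulin. Lower were 10 STAT3, 4 interferon-stimulated, 11 differentiation, 20 ATF4, 13 chaperone, 3 cholesterol, 9 NRF2, 9 glycolysis, 13 hnRNP and 26 ribosomal genes; edgeR then called 0 mitochondrially encoded mRNAs, of which 1 was higher and 1 lower at an unadjusted p under 0.05. Other counts were the same.

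**Figure D4:**
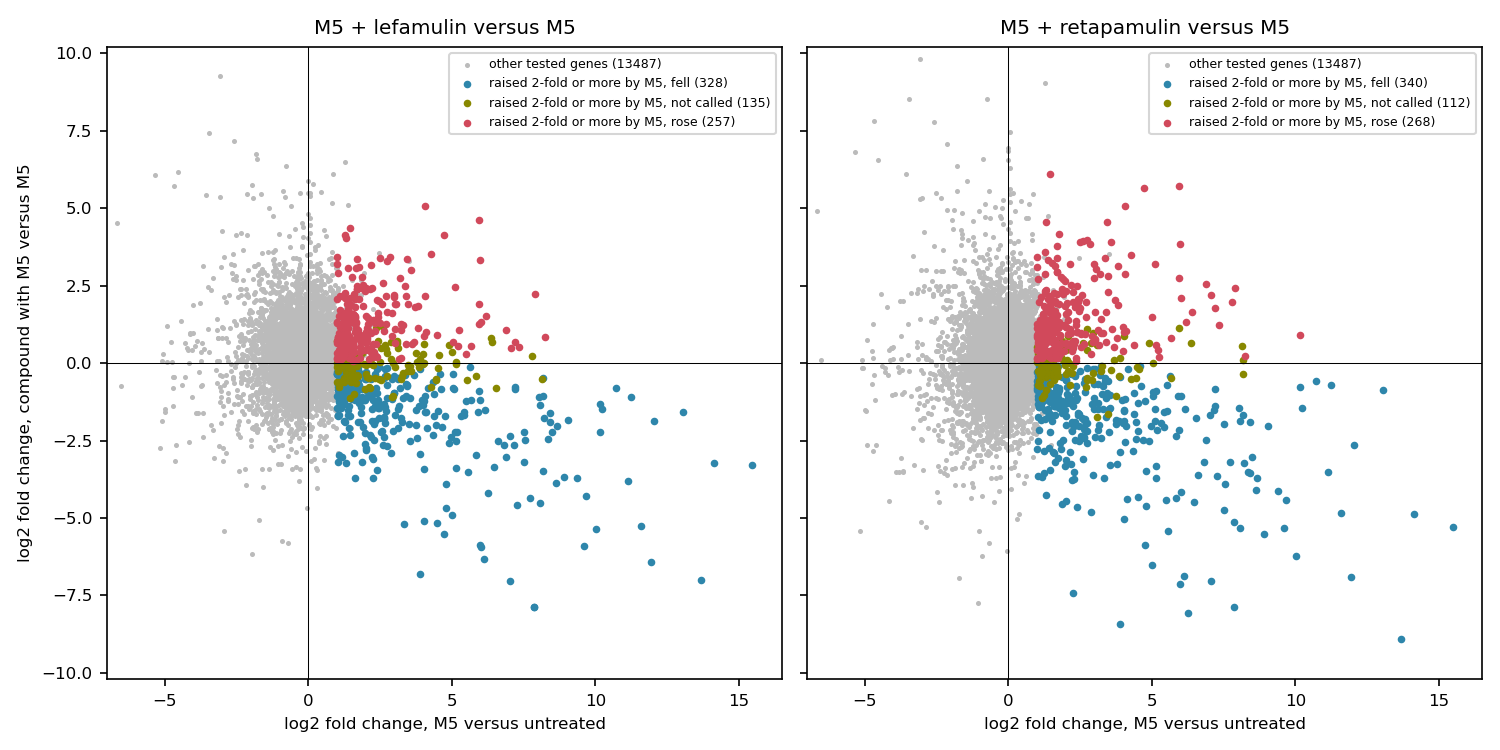
Log2 fold change of each tested gene in M5 against untreated (x axis) and in each compound with M5 against M5 (y axis), with the 720 genes that M5 raised at least 2-fold coloured by their call with the compound. With lefamulin 328 of them fell, 257 rose and 135 were not called, and with retapamulin 340 fell, 268 rose and 112 were not called.

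How the compounds moved the genes that M5 had changed was counted from the same tests. More of the genes that M5 raised at least 2-fold fell with the compounds than rose further, whereas over all genes that M5 raised more rose further than fell. Of 720 genes that M5 raised at least 2-fold, 328 fell, 257 rose further and 135 were not called with lefamulin, and 340, 268 and 112 with retapamulin. Over all 14207 genes tested, edgeR called 4873 lower and 4774 higher with lefamulin, and 5404 lower and 4842 higher with retapamulin. The overlap of independent lists was not computed for the 720 genes. HAS3 fell from 949.5 ± 24.2 CPM to 191 ± 4.37 and 133 ± 4.60 CPM, whereas IER3, which M5 raised to 302 ± 2.58 CPM, rose further to 513 ± 11.9 and 683 ± 15.8 CPM. Relative to untreated cells, 623 of the 720 genes were still called higher with M5 and lefamulin, 75 were not called and 22 were called lower; with retapamulin the numbers were 583, 95 and 42. Of 785 genes that M5 lowered at least 2-fold, 242 rose, 163 fell further and 380 were not called with lefamulin, and 199, 233 and 353 with retapamulin.

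Over all 4022 genes that M5 raised, 1455 fell and 1805 rose with lefamulin, and 1421 fell and 1978 rose with retapamulin. Independent lists would give 1379.5 and 1529.9 genes that fell, and the simulations, chance with no effect, gave at most 1. For the 1805 and 1978 genes that rose further, the overlap of independent lists was not computed. With separate M5 libraries the counts that fell were 1064 to 1201 and 1036 to 1136. On log2 FPKM with the filter, 959 and 948 genes fell with lefamulin at pseudocounts of 1 and 0.1. Of the 3817 genes that M5 lowered, 1125 rose with lefamulin and 1071 with retapamulin, against 1282.6 and 1300.9 for independent lists and 789 to 818 and 768 to 816 with separate M5 libraries. More of them fell further, 1542 with lefamulin and 1817 with retapamulin. For these further falls the overlap of independent lists was not computed. Across genes the covariance of the M5 change with the change by the compound was -0.146 for lefamulin and -0.0996 for retapamulin, against -0.0285 and -0.0284 in the simulations.

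Cells given M5 with a compound were also compared with untreated cells, to see how far they lay from them. With lefamulin edgeR called 5244 genes higher and 5275 lower, of which 1759 and 1355 changed at least 2-fold. With retapamulin it called 5337 higher and 5817 lower, of which 1895 and 2051 changed at least 2-fold. TNF stayed above untreated cells, by 2.73 (SE 0.25) with lefamulin and 2.49 (SE 0.25) with retapamulin, and HNRNPU lay below them, by -0.43 (SE 0.03) and -0.38 (SE 0.03). The shares of higher genes were 49.9% and 47.8%, but 38.6% and 33.7% on library totals. The groups did not overlap for 10818 (76.1%) and 11257 genes (79.2%), against 10% by chance.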

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

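The minimum of 1.5-fold in each direction for naming genes here was chosen after the values were seen, while the test between the compounds was set before the data were examined. Lefamulin and retapamulin moved 130 genes in opposite directions against M5 with the difference itself called by edgeR, clone names, LOC numbers and pseudogenes left out. Directions of small changes depend on the scaling: with retapamulin the median of all genes was -0.05 with TMM and -0.19 on library totals. RPLP0 and RPS3, which are among the 130, turned from rise to fall with retapamulin on library totals. The count was not repeated under other scalings. With at least 1.5-fold each way there were 9 such genes, given with the log2 difference of lefamulin minus retapamulin. IL24, a cytokine of the IL-10 family that M5 raised, differed by -2.24 (SE 0.10), with 13.7 ± 0.215 CPM after M5, 5.46 ± 0.566 with lefamulin and 25.8 ± 1.84 with retapamulin. HSPA2, a heat shock protein of the HSP70 family, differed by 1.53 (SE 0.11), with 6.72 ± 0.542, 10.3 ± 0.300 and 3.58 ± 0.354 CPM. DHRS9, a short-chain dehydrogenase, differed by -1.20 (SE 0.14), RGS7, a regulator of G protein signalling, by -1.84 (SE 0.20), and H2BC21, a histone gene, by 1.54 (SE 0.17). Levels at or under 2.15 CPM in M5 and compound groups lay behind the differences of APOLD1 (2.03, SE 0.31), DUSP19 (1.83, SE 0.39), PIK3R3 (1.58, SE 0.30) and CD27-AS1 (1.99, SE 0.30), the last uncertain because strandedness was not stated.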

How the results depend on the processing

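Library totals alone and separate M5 libraries were chosen after seeing the data, and the other settings before. Counts of called genes over each leave-one-out were 7263 to 7544 for M5 against untreated, 9177 to 9404 and 9817 to 10001 for lefamulin and retapamulin against M5, 4787 to 5140 between the compounds, and 10171 to 10326 and 10795 to 10985 for lefamulin and retapamulin against untreated. Of M5-raised genes 1336 to 1483 and 1284 to 1450 then fell with lefamulin and retapamulin, and of M5-lowered genes 1004 to 1107 and 962 to 1080 rose. Genes called in the same direction with both compounds numbered 8013 to 8216, and called lists 109 to 114 against 113. Under RLE, DESeq2, other filters, fits of 2 groups, library totals alone and log2 FPKM the counts of genes stayed within 1.5 times, except that 959 and 948 M5-raised genes fell with lefamulin on log2 FPKM with pseudocounts of 1 and 0.1. On library totals alone, which like FPKM leave out the TMM factors, 1030 fell, and other causes were not tested. Of these settings the lists were rerun under RLE alone, with 113 called. A minimum of 1 on the log2 scale left, by its construction, 1505, 1988, 2624, 462, 3114 and 3946 called genes in the order above. It left 194 and 229 M5-raised genes that fell with lefamulin and retapamulin, 170 and 147 M5-lowered genes that rose, and 1634 genes in the same direction.

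With a replicate block, which treats equal replicate numbers as a pairing, the counts were 7780, 9578, 10212, 5611, 10493 and 11119 in that order. M5-raised genes that fell numbered 1441 and 1402, M5-lowered genes that rose 1116 and 1067, genes in the same direction 8344, and called lists 115. Aryl hydrocarbon receptor targets in M5 against untreated turned from upward to downward with the block (adjusted p = 0.00149, within 0.00149 to 0.776); the cause was not tested. Correlations of replicates of equal number across groups ranged from -0.144 to 0.184, with 3 of 18 over 0.1, and 11 of 36 best matches fell on the same number.

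Of 113 called lists, 73 held with camera and a preset correlation and 32 with an estimated correlation. Turned in direction were cytokines (adjusted p = 0.740 preset and 0.742 estimated), pregnane X receptor targets (0.999771 and 0.999776) and TGF-beta genes (0.909 and 0.964) with lefamulin, STAT3 genes with retapamulin (0.909 and 0.953) and NF-kB genes between the compounds (0.793 and 0.923). Over all alternatives these ranged from 3.9e-08 to 0.742, 0.0282 to 0.999776, 0.00952 to 0.964, 2.5e-05 to 0.953 and 0.0046 to 0.923. The cause was not tested.

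Of gene-level results, 5 turned in direction on log2(FPKM + 1) with and without the filter, log2(FPKM + 0.1) and library totals alone. RPS9 in M5 versus untreated lay at -0.0297 with either filter, -0.0298 at the smaller pseudocount and -0.0304 on library totals. In that order, with retapamulin against M5, BAG3 lay at -0.00611, -0.00618 and -0.00641, NQO1 at -0.0405, -0.0410 and -0.0411, RPLP0 at -0.0123 in each, and RPS3 at -0.0218, -0.0218 and -0.0219. All these settings leave out the TMM factors, and library totals alone differ from the main fit in that step only. In the leave-one-out fits 2744 gene results kept their direction and call, 57 lost the call and 1 gained it. The median SE was 0.07, and replicates differed by a chi-square per gene of 2.78 to 8.84, where counting error alone would give about 1; the share of depth in the SE was not tested.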

Other observations

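The tests of scaling, of solvent, of the trend for cholesterol genes and of the shared M5 libraries for M5-raised genes of any size were chosen after the results were seen.

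Mitochondrially encoded mRNAs were split with each compound. Of 13 genes 5 rose and 3 fell with lefamulin (median -0.05, -0.10 on library totals, mean 0.09, fry upward, adjusted p = 0.312), and 5 rose and 4 fell with retapamulin (median 0.08, -0.06 on library totals, adjusted p = 0.244), and neither list call passed. With a replicate block both passed (0.0122 and 0.00987), within 0.0122 to 0.946 and 0.00987 to 0.923 over the alternatives. ND3, a subunit of complex I, rose from 661 ± 64.2 CPM with M5 to 1369 ± 128 and 1328 ± 133 CPM, and ND2 rose by 0.62 (SE 0.06) and 0.57 (SE 0.06). ND5, of the same complex, fell from 1558 ± 135 to 1156 ± 94.8 and 1182 ± 57.2 CPM. Between the compounds ND2, ND3 and ND5 differed by 0.05, 0.04 and -0.03, none of them called, and of the 13 genes CYTB alone was called, lower with lefamulin (-0.12, SE 0.05), which was named after its values were seen.

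HNRNPU moved with much of its family. The median of the 23 hnRNP members was -0.37 with lefamulin (range -0.69 to -0.04) and -0.23 with retapamulin (-0.75 to 0.19), against -0.58 and -0.53 for HNRNPU. In M5 against untreated HNRNPU was member 19 of 23 from the lowest, with a family median of 0.05 that was -0.07 on library totals.

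The rise of cholesterol genes with both compounds was weighed first. Between 3 scalings the list median differed by at most 0.17 and stayed at or above 1.97. A scaling shifts all genes alike, so this shows only that the rise was larger than the differences between these scalings. After removal of a trend with abundance, length and GC content, which took 1.31% and 2.06% of the variance of all genes, the median residual was 2.33 and 2.07 (quartiles 1.98 to 2.84 and 1.61 to 2.38). The trend shifted genes by a median of only 0.07 and 0.10, so this shows only that the rise was larger than this weak trend. The labels of 0 samples named a solvent, so an effect of solvent cannot be told apart from that of the compounds, and a response to each compound may be a candidate explanation that stays untested.

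The split of genes that M5 raised at least 2-fold was weighed next. Chance values of the shared M5 libraries would lose the genes that fell when separate M5 libraries were used, but at least 0.926 times as many fell. Over M5-raised genes of any size the lowest ratio was 0.729, in fits with fewer M5 libraries, so part of those that fell may come from the shared libraries. After removal of the trend, 27.2% of the 635 genes raised by M5 at least 2-fold and with a GC content kept a residual above 0.5 with lefamulin and 43.0% one below -0.5, against 32.3% and 43.8% with retapamulin. No group was given a compound without M5. These data therefore cannot tell whether the compounds act on the M5 response itself or on other genes. Timing was not tested.

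The larger fall of DNA replication genes than of mitosis genes was weighed last. The medians of the 2 lists differed by -0.61 with lefamulin and -0.60 with retapamulin. The difference of list means went from -0.78 ± 0.04 with M5 to -1.58 ± 0.01 and -1.53 ± 0.02, with no overlap of libraries. After removal of the trend the medians differed by -0.62 and -0.56. The trend shifted genes by a median of only 0.07 and 0.10, so this shows only that the difference was larger than this weak trend. If a smaller share of cycling cells lowered both lists about alike, it would not by itself give the difference. Medians were -0.95 and -1.05 for replication genes, against -0.34 and -0.45 for mitosis genes. Whether a smaller share lowers the lists alike was not tested, so it stays open as a cause. A shift of cells between cell cycle phases may be a candidate explanation, and was not tested.

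Other splits of the 6 libraries of each comparison into 3 and 3 were counted, and 10 splits are too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes. It called 7839 genes for M5 against untreated, 9647 and 10246 for lefamulin and retapamulin against M5, 5689 between the compounds, and 10519 and 11154 for lefamulin and retapamulin against untreated. The highest of the other splits was 0 by edgeR in each comparison, with at most 877, 283, 462, 624, 265 and 301 genes at an unadjusted p under 0.05. Each other split mixes the groups, so the difference between them enters the spread within the mixed groups and holds down the calls. For this reason too the splits cannot tell whether chance plays a part.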
